A study of Mus musculus with 12 samples.

How the data were processed

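RNA was measured in interscapular brown adipose tissue of 12 female C57BL/6 mice aged 12 weeks and held for 2 weeks at 30 °C, 1 array per mouse. Mice with floxed Cpt2 alleles served as wild-type controls, and knockouts also carried Cre under the adiponectin promoter, which acts in adipocytes. Each mouse received saline or 10 mg/kg CL316243 by intraperitoneal injection, and tissue was taken 3 h later. The 4 groups (wild type or knockout, saline or CL316243) hold 3 mice each and come from the sample labels, which do not pair mice between groups and give no batch. Replicate numbers are referred to here as array 1, 2 and 3 of a group.

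The deposited values are log2 signals of transcript clusters, called probe sets in the report, from an Affymetrix mouse exon array, normalized by RMA in Partek per the submitters' processing notes, which name genome build mm9 and give no software versions. The values were used as deposited, with no further normalization, after their scale was checked against the files. The table holds 115830 rows. The probe table used here lists 27839 of them: 25539 belong to 1 gene and 2300 to several genes, and 87991 are not listed. Only clusters of 1 gene were used, which covered 20259 genes, and where a gene had several clusters the one with the highest mean over all arrays was taken. Genes were tested if they exceeded the 25th percentile of named genes of an array in at least 3 arrays, which left 15896 genes, 2797 with several clusters. No coordinates are reported, because the gene table used here is on another build than the one the notes name.

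In all, 5 contrasts were estimated: the CL316243 effect in each genotype, the knockout effect after each injection, and the interaction, the CL316243 effect in knockouts minus that in wild types. A linear model with 1 mean per group was fitted to each gene with limma 3.58.1 in R 4.3.3 and moderated with empirical Bayes (prior degrees of freedom 3.14, residual 8). P-values were adjusted by Benjamini and Hochberg over all tested genes within a contrast, and genes under 0.05 are said to rise, fall or differ. Errors beside log2 differences are standard errors of the fit. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made tables and figures.

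Before the data were examined, 31 gene lists with 742 genes, the comparisons, the tests, the alternatives and a rule for naming genes were fixed. Lists were written from general knowledge, 645 of their genes had a cluster of their own, and the 30 lists with at least 5 tested members were tested as lists, while Cpt2 stood alone. They cover adipocyte identity, adrenergic signalling, metabolism, mitochondria, stress responses, the clock, proliferation and markers of other cell types. Each list was tested against the other genes with camera (preset correlation 0.01), again with the correlation estimated from the residuals, and with the rotation test fry. Members past the adjusted p over all genes are counted, and beside them those past it when adjusted over the list alone. The rule picked the 10 largest rises and falls without overlap between groups, up to 4 genes per list and a panel of 26 genes fixed beforehand. The report covers the panel with and without a call, and describes only a part of the list genes and largest differences, mostly those whose call held under the alternatives, a choice made after their values were seen. Of the panel, 21 were tested: no row of the probe table used here was matched to Adrb3, Gdf15 or Gyk, Cpt1b shared its cluster with another gene and Il6 lay below the filter.

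The alternatives were median-centring or quantile-normalizing the arrays again, no filter or a filter at the 50th percentile, the mean of a gene's clusters, trended and robust moderation, ordinary least squares, fitting only the groups compared, array weights, replicate number as a block, 2 other thresholds and leaving out each array in turn. Array weights were computed gene by gene, which was chosen after the usual method had not converged, and a skeletal muscle covariate, with and without knockout saline array 1, was added after the data had been seen. The model was tested on simulated data built from the residuals, with 200 of 15896 genes changed per contrast: at a size of 1 log2 unit it recovered 92.5, 93.5, 91.0, 90.0 and 81.0% of them in the 5 contrasts in the order above, and at 0.5 log2 units 29.5, 27.0, 31.5, 25.0 and 0%. Camera there called 1 of 1 shifted lists and 0 of 19 others, leaving its preset correlation untested. The 3 arrays per group limit precision.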

Results

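The arrays compared brown fat of wild-type and adipocyte-specific Cpt2 knockout mice, 3 h after saline or 10 mg/kg CL316243, an agonist of the β3-adrenergic receptor, with 3 mice per group. Signals correlated across the 15896 tested genes at Pearson r of 0.937 to 0.984 within groups and 0.878 to 0.960 between them. The first principal component (35.0% of the variance) set all 6 knockout arrays apart from the wild-type arrays, at scores of 17.6 to 31.5 after saline and 10.1 to 16.9 after CL316243, against -7.62 to 1.50 and -40.9 to -34.0. The second (27.2%) followed the agonist, with scores of 13.3 to 36.3 and 3.60 to 14.6 in the saline groups and -10.7 to -4.06 and -35.1 to -22.4 in the CL316243 groups of wild types and knockouts.

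Cpt2 encodes the enzyme of the inner mitochondrial membrane that completes the import of long-chain fatty acids for oxidation. Its log2 signal was 8.83, 8.99 and 8.75 in the wild-type saline arrays, 8.60, 8.83 and 8.52 in the wild-type CL316243 arrays, 8.06, 8.20 and 8.06 in the knockout saline arrays and 7.91, 7.87 and 7.92 in the knockout CL316243 arrays, so each knockout array lay below each wild-type array. The knockout difference was -0.75 ± 0.096 after saline (log2, standard error, n = 3 per group, adjusted p = 0.00207) and -0.75 ± 0.096 after CL316243 (adjusted p = 3.86e-04). The sources used here do not place the array's probes relative to the deleted part of the gene, and cells other than adipocytes keep the gene, so the size of this drop does not measure how complete the deletion was.

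Ucp1, the uncoupling protein that makes heat in brown fat, was at 12.60, 12.94 and 12.07 in wild-type saline, 13.59, 13.68 and 13.60 in wild-type CL316243, 8.39, 12.29 and 11.47 in knockout saline and 10.69, 11.70 and 11.90 in knockout CL316243 arrays. Knockout saline array 1 stood apart, with Dio2, the deiodinase that activates thyroid hormone, also low there (values 6.43, 9.02 and 7.81), and Ucp1 had no call in the 5 comparisons. After CL316243 the knockout difference of Ucp1 was -2.19 ± 0.76 (adjusted p = 0.0509), and over the alternatives tried its adjusted p ran from 0.00116 to 0.159, at 0.00116 without that array. The effect of the agonist on Ucp1 in wild types was 1.08 ± 0.76 (adjusted p = 0.331, 0.0307 without that array, 0.0121 to 0.541 over the alternatives). Skeletal muscle markers also varied from array to array, with mean centred scores from -2.10 to 1.94, the extremes both in wild-type saline.

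**Figure D1:**
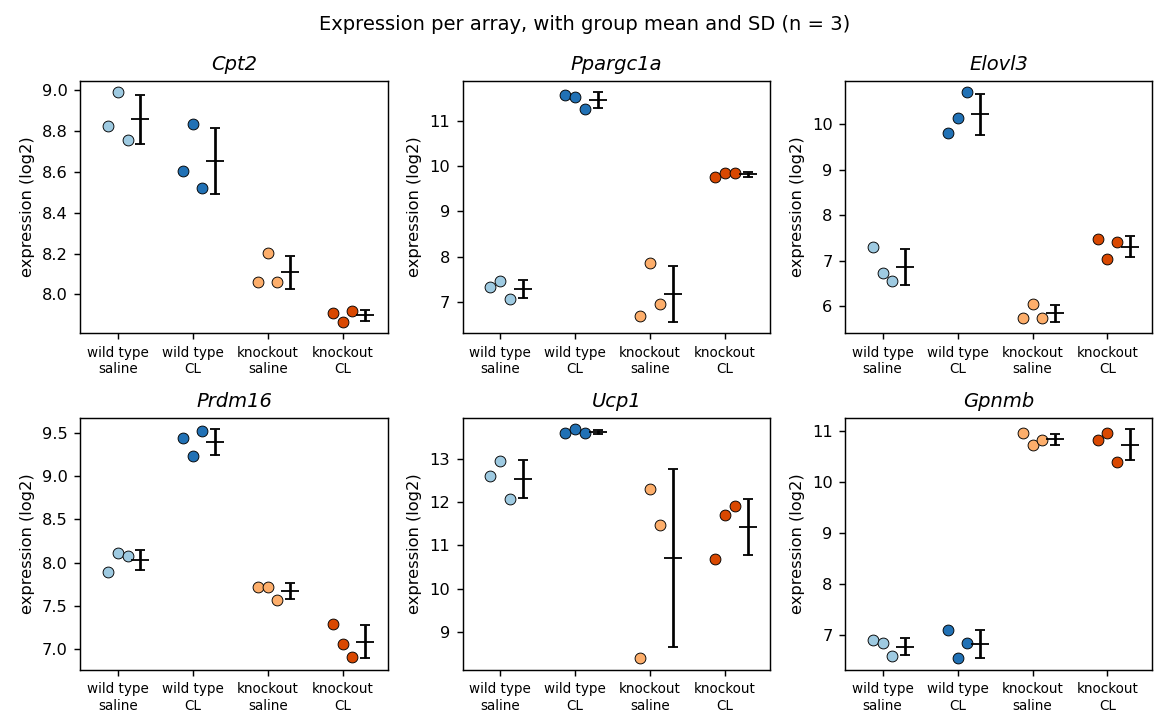
Log2 expression of 6 genes in each of the 12 arrays, by genotype and treatment, with group means and standard deviations beside the points (n = 3). Ppargc1a rose after CL316243 in both genotypes, by 4.17 in wild types and 2.64 in knockouts, while Gpnmb was higher in knockout arrays after either injection.

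Wild-type brown fat responded broadly to the agonist. Ppargc1a, the coactivator that switches on mitochondrial and thermogenic genes, rose 18.0-fold (log2 difference 4.17 ± 0.24, standard error, n = 3 per group, adjusted p = 2.52e-06). Elovl3, an elongase of very long fatty acids in brown fat, rose by 3.36 ± 0.24, and Prdm16, a transcription factor of brown adipocyte identity, rose by 1.36 ± 0.11. Of the cytosolic heat shock genes 10 of 12 rose, and of the cAMP-responsive genes 21 of 35. Lep, the leptin gene, fell by 1.71 ± 0.18, and the guanylate-binding protein gene Gbp11 fell by 3.19 ± 0.60.

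The other largest rises were those of the stress-induced kinase Plk3 (3.77 ± 0.20), the transcript 3930402G23Rik (3.40 ± 0.19), the chaperones Hsph1 (3.06 ± 0.16) and Hspa1a (3.00 ± 0.46), the growth-arrest gene Gadd45g (2.97 ± 0.31), the insulin receptor adaptor Irs2 (2.95 ± 0.27), the nuclear receptor Nr4a3 (2.91 ± 0.36) and the lysophospholipid transporter Mfsd2a (2.79 ± 0.22). Hspa1a has a near-identical neighbour gene, and which copy the probes read is uncertain. The largest falls after Gbp11 were in Apol6 (-3.18 ± 0.24), Aplnr (-3.07 ± 0.20) and BC023105 (-3.06 ± 0.47), in the G-protein regulator Rgs2 (-2.37 ± 0.31), in Gbp2 (-2.29 ± 0.23), in the secreted C1q relative C1qtnf9 (-2.27 ± 0.23) and in 5830467E07Rik (-2.21 ± 0.19). The death ligand Tnfsf10 (-2.70 ± 0.22) and the zinc finger gene Zfp820 (-2.08 ± 0.44) had smaller differences when the mean of each gene's probe sets was taken, of -1.31 and -1.17 on the log2 scale. The Zfp820 arrays lay under the expression floor after CL316243 (mean 3.81), so the size of its fall is uncertain.

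Among the gene lists, cAMP-responsive and immediate-early genes moved most clearly, with Atf3 (2.21 ± 0.18), Klf4 (2.03 ± 0.16), Nfil3 (1.86 ± 0.15) and Cebpb (1.85 ± 0.15). Of 35 tested cAMP-responsive genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone). Their median was 0.70, with camera adjusted p = 3.48e-13 and adjusted p = 0.383 with an estimated correlation. Cytosolic heat shock genes rose nearly as a body, among them Dnajb1 (2.15 ± 0.14), Bag3 (1.79 ± 0.15) and Hsp90aa1 (1.58 ± 0.14). Of 12 tested heat shock genes, 10 rose (10 adjusted over the list alone). Their median was 1.32, with camera adjusted p = 4.29e-10 and adjusted p = 0.323 with an estimated correlation. The brown adipocyte list rose, including Ppara (1.56 ± 0.31) and Zfp516 (0.63 ± 0.083), and its median was 0.27 without wild-type saline array 3. Of 26 tested brown adipocyte genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). Their median was 0.48, with camera adjusted p = 1.38e-04 and adjusted p = 0.576 with an estimated correlation. PPAR targets rose (median 0.59 with the mean of each gene's probe sets), for example the peroxisomal enzyme Ehhadh (1.59 ± 0.18), the thioesterase Acot2 (1.14 ± 0.13), the droplet coat Plin2 (1.60 ± 0.12) and the hormone Fgf21 (1.28 ± 0.11). Of 19 tested PPAR targets, 7 rose and 1 fell (11 and 1 adjusted over the list alone). Their median was 0.34, with camera adjusted p = 4.14e-06 and adjusted p = 0.383 with an estimated correlation. Endothelial markers rose too, with Flt1 (0.90 ± 0.12), Eng (0.80 ± 0.11) and Cdh5 (0.51 ± 0.073). Of 17 tested endothelial markers, 9 rose and 3 fell (9 and 3 adjusted over the list alone). Their median was 0.38, with camera adjusted p = 4.04e-04 and adjusted p = 0.576 with an estimated correlation.

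The fatty acid and cholesterol synthesis lists moved the other way in wild types. The fatty acid synthesis list fell, with the regulators Mlxipl (-0.80 ± 0.13) and Mid1ip1 (-0.77 ± 0.18) and the lipase relative Pnpla3 (-1.46 ± 0.27), while the elongase Elovl5 (0.62 ± 0.14) rose. Of 24 tested fatty acid synthesis genes, 1 rose and 11 fell (1 and 12 adjusted over the list alone). Their median was -0.59, with camera adjusted p = 0.0259 and adjusted p = 0.898 with an estimated correlation. That call ended without wild-type saline array 1 (adjusted p = 0.167) or wild-type CL316243 array 3 (0.178), with the stricter filter (0.0580) and with array weights (0.0532), and its adjusted p ran from 0.00335 to 0.178 over the alternatives. Cholesterol synthesis genes fell, as in Stard4 (-0.61 ± 0.11) and Fdps (-0.43 ± 0.088), although the synthase Hmgcs1 (1.18 ± 0.23) rose. Of 19 tested cholesterol synthesis genes, 1 rose and 11 fell (1 and 14 adjusted over the list alone). Their median was -0.43, with camera adjusted p = 0.00569 and adjusted p = 0.701 with an estimated correlation. White adipocyte genes fell, with Hoxc6 (-1.31 ± 0.10) and Igf1 (-0.70 ± 0.13), a call that ended with array weights (median -0.25, adjusted p = 0.0532, 0.00410 to 0.0532 over the alternatives), and the median was -0.24 with no filter. Of 17 tested white adipocyte genes, 7 fell (7 adjusted over the list alone). Their median was -0.36, with camera adjusted p = 0.0126 and adjusted p = 0.610 with an estimated correlation.

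Smaller list shifts accompanied these. The lipolysis and lipid droplet list, which also holds triacylglycerol synthesis genes, rose, with Hilpda (2.16 ± 0.14) and Abhd5 (0.86 ± 0.076). Its medians were 0.099 without wild-type saline array 3, 0.34 without wild-type CL316243 array 1 and 0.11 without array 2. Of 29 tested lipolysis and droplet genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone). Their median was 0.19, with camera adjusted p = 0.00110 and adjusted p = 0.610 with an estimated correlation. Adrenergic signalling genes rose, among them the cyclase Adcy3 (1.52 ± 0.095) and the scaffold Akap12 (2.15 ± 0.14), at 0.16 without wild-type saline array 1 and 0.13 without wild-type CL316243 array 1. Of 24 tested adrenergic signalling genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone). Their median was 0.24, with camera adjusted p = 0.00336 and adjusted p = 0.323 with an estimated correlation. Endoplasmic reticulum stress genes rose, as in Dnajb9 (1.23 ± 0.15) and Hspa5 (0.75 ± 0.090), at 0.27 without wild-type CL316243 array 3 and with array weights. Of 21 tested endoplasmic reticulum stress genes, 7 rose (7 adjusted over the list alone). Their median was 0.17, with camera adjusted p = 0.00110 and adjusted p = 0.610 with an estimated correlation. The integrated stress response rose, with Atf4 (1.03 ± 0.11) and Slc3a2 (1.20 ± 0.075), at 0.056 without wild-type saline array 2 and 0.19 without array 3, 0.19 after quantile normalization and 0.20 with the stricter filter. Of 24 tested integrated stress response genes, 8 rose and 3 fell (8 and 4 adjusted over the list alone). Their median was 0.11, with camera adjusted p = 0.00569 and adjusted p = 0.383 with an estimated correlation. The other lists did not pass (adjusted p from 0.175 to 0.991). Of these, skeletal muscle and fibroblasts and matrix passed camera under at least 1 alternative.

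Limma's moderated test called 4735 of 15896 genes at an adjusted p under 0.05, 1743 higher and 2992 lower after the agonist, and 458 of them by at least 2-fold (291 higher and 167 lower). The share higher was 36.8% as deposited and 49.9% after quantile normalization over the tested genes, so that balance is relative to the deposited scaling. Over all 5 comparisons camera called 65 of 150 list results at its preset correlation and 0 at the estimated one. There the lowest adjusted p was 0.144, and 14 had an unadjusted p under 0.05. The test fry, which asks whether a list moves in one direction against residual variation, called 40 of the 150, 37 together with camera. These were 11 of 12 camera calls for CL316243 in wild types, 2 of 9 in knockouts and 3 of 16 for the interaction. For genotype they were 7 of 10 after saline and 14 of 18 after CL316243.

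Knockout brown fat also responded to the agonist. Ppargc1a rose 6.22-fold (2.64 ± 0.24 on the log2 scale, n = 3 per group, adjusted p = 1.39e-04) and Elovl3 rose by 1.47 ± 0.24 (adjusted p = 0.00259). The largest rise was that of the secreted lubricin gene Prg4, at 3.37 ± 0.14, and the lipid droplet gene Hilpda (2.37 ± 0.14) rose as well. Of the integrated stress response genes 11 of 24 rose, and 8 of 22 genes of mitochondrial β-oxidation fell, with the dehydrogenases Acadm (-0.50 ± 0.11) and Hadh (-0.50 ± 0.10). The brown adipocyte factor Ebf2 (-0.65 ± 0.089) fell as well.

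Other large rises were in the pentraxin Ptx3 (2.49 ± 0.48), the alarmin cytokine Il33 (2.36 ± 0.34), Fam110c (2.32 ± 0.17), the sugar nucleotide dehydrogenase Ugdh (2.28 ± 0.16), the kinase anchor Akap2 (2.26 ± 0.22) and the imprinted gene Peg10 (2.17 ± 0.23). The transcript A530006G24Rik (3.04 ± 0.36) was at 1.54 with the mean of its probe sets. The largest falls were in the immunoglobulin kappa variable genes Igkv6-25 (-3.39 ± 0.59) and Igkv4-72 (-2.67 ± 0.40), followed by Aplnr (-2.16 ± 0.20), the natural killer receptor Ncr1 (-1.89 ± 0.25), Zfp964 (-1.82 ± 0.36), A530020G20Rik (-1.79 ± 0.18), C1qtnf9 (-1.78 ± 0.23) and Rgs2 (-1.60 ± 0.31). With the mean of their probe sets Zfp820 (-1.94 ± 0.44) was at -1.18, and Tnfsf10 (-1.67 ± 0.22) was at -0.57 and lost its call. The Zfp820 arrays again lay under the floor after CL316243 (mean 4.79), as did 2 of 3 Fam110c arrays after saline (mean 5.34), so the sizes of these changes are uncertain.

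The integrated stress response rose in knockouts and kept its call with each array left out, with the amino acid transporters Slc7a1 (1.26 ± 0.11), Slc7a5 (0.88 ± 0.11) and Slc3a2 (0.50 ± 0.075) and the hormone Fgf21 (0.96 ± 0.11). Of 24 tested integrated stress response genes, 11 rose (12 adjusted over the list alone). Their median was 0.39, with camera adjusted p = 5.41e-07 and adjusted p = 0.144 with an estimated correlation. Heat shock genes rose, with Hsph1 (1.78 ± 0.16), Bag3 (1.20 ± 0.15), Dnajb1 (1.13 ± 0.14) and Hsp90aa1 (0.94 ± 0.14). Of 12 tested heat shock genes, 5 rose (6 adjusted over the list alone). Their median was 0.72, with camera adjusted p = 8.14e-06 and adjusted p = 0.824 with an estimated correlation. Inflammatory genes rose, among them P-selectin Selp (1.50 ± 0.14) and the cytokine inhibitor Socs3 (0.87 ± 0.15), while haptoglobin Hp (-0.68 ± 0.11) fell. Of 28 tested inflammatory genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). Their median was 0.48, with camera adjusted p = 1.00e-04 and adjusted p = 0.824 with an estimated correlation. cAMP-responsive genes rose, with Nfil3 (2.14 ± 0.15), Fosl1 (1.95 ± 0.18) and Pde4d (0.77 ± 0.12), at 0.24 without knockout saline array 1. Of 35 tested cAMP-responsive genes, 14 rose and 2 fell (14 and 2 adjusted over the list alone). Their median was 0.38, with camera adjusted p = 1.60e-06 and adjusted p = 0.824 with an estimated correlation. Endoplasmic reticulum stress genes rose, as in Xbp1 (0.58 ± 0.095) and Hspa5 (0.53 ± 0.090), at 0.12 without knockout CL316243 array 1. Of 21 tested endoplasmic reticulum stress genes, 2 rose (2 adjusted over the list alone). Their median was 0.21, with camera adjusted p = 9.55e-04 and adjusted p = 0.824 with an estimated correlation. Single antioxidant genes rose in knockouts, Mt2 (1.56 ± 0.21) and Hmox1 (1.42 ± 0.21), without a call for their list.

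Mitochondrial lists fell in knockouts after the agonist, but rested on single arrays. Mitochondrial β-oxidation and the respiratory chain (4 fell of 41 tested, 0 adjusted over the list alone and 16 lower at an unadjusted p under 0.05) lost their calls without knockout saline array 2 (medians -0.15 and -0.12, adjusted p = 0.176 and 0.193), and without knockout saline array 1 the medians were -0.50 and -0.36. Of 22 tested mitochondrial β-oxidation genes, 8 fell (8 adjusted over the list alone). Their median was -0.30, with camera adjusted p = 0.00564 and adjusted p = 0.824 with an estimated correlation. Respiratory chain genes had a median of -0.24, with camera adjusted p = 9.55e-04 and adjusted p = 0.824 with an estimated correlation. Over the alternatives their adjusted p ran from 3.99e-06 to 0.176 and from 1.18e-08 to 0.193. Fatty acid synthesis fell, with Thrsp (-1.17 ± 0.26) and Mlxipl (-0.74 ± 0.13) and the regulator Srebf1 (adjusted p = 0.00961), and lost its call without knockout saline array 1 (median -0.12), knockout CL316243 arrays 1 (-0.25) or 3 (-0.29), wild-type saline array 2 or wild-type CL316243 arrays 1 or 3 (-0.30 each), and with the muscle covariate (-0.24), the stricter filter (-0.30) or array weights (-0.33), and was at -0.51 without knockout saline array 2. Of 24 tested fatty acid synthesis genes, 5 fell (6 adjusted over the list alone). Their median was -0.30, with camera adjusted p = 0.0499 and adjusted p = 0.824 with an estimated correlation. Fibroblast and matrix genes rose, with Thbs1 (2.01 ± 0.36) and Timp1 (1.14 ± 0.25), at 0.064 and with no call without knockout saline array 2 and at 0.24 without knockout CL316243 array 3. Of 22 tested fibroblast and matrix genes, 5 rose (5 adjusted over the list alone). Their median was 0.13, with camera adjusted p = 0.00787 and adjusted p = 0.824 with an estimated correlation. The other lists did not pass (adjusted p from 0.0684 to 0.967). Of these, brown adipocyte identity and thermogenesis, PPAR targets, lipolysis and lipid droplets, the tricarboxylic acid cycle, lymphocytes, endothelium and skeletal muscle passed camera under at least 1 alternative.

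Limma's moderated test called 2851 of 15896 genes at an adjusted p under 0.05, 1232 higher and 1619 lower after the agonist, and 233 of them by at least 2-fold (176 higher and 57 lower). The count moved with single arrays, to 1707 without knockout saline array 1 and to 1591 and 1730 without knockout CL316243 arrays 1 and 3. The responses of the 2 genotypes share no arrays: 710 genes rose in both and 1085 fell in both, against 135 and 305 if the calls were independent, and 47 were called in opposite directions (Pearson r = 0.575 over all tested genes).

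After saline, 14 of 20 macrophage markers were higher in knockout than in wild-type brown fat. Gpnmb, a glycoprotein of lipid-laden macrophages, was 16.6-fold higher (4.06 ± 0.17, n = 3 per group, adjusted p = 1.02e-06), and the lysosomal proton pump subunit Atp6v0d2 was higher by 2.86 ± 0.18 (adjusted p = 4.59e-05). The lipid-sensing receptor Trem2 (1.83 ± 0.16) and the lysosomal glycoprotein Cd68 (1.58 ± 0.12) were higher with them. Of the respiratory chain genes 32 of 41 were lower (36 adjusted over the list alone).

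The largest differences included the immunoglobulin kappa variable genes Igkv4-72 (4.75 ± 0.40) and Igkv6-25 (4.42 ± 0.59) and another not named here (4.81 ± 0.69), members of a family of near-identical sequences that probes do not always separate. Their wild-type saline means were 4.29, 6.17 and 6.48, against expression floors of 5.27 to 5.58 on the arrays, so the size of the Igkv4-72 difference is uncertain. Catspere2 (4.72 ± 0.72) was at 1.67 with the mean of its probe sets, and its size is also uncertain, with 2 of 3 wild-type arrays under the floor (mean 5.35). The interleukin 7 receptor Il7r (2.10 ± 0.36), neuronatin Nnat (2.09 ± 0.18) and the aminopeptidase Anpep (2.08 ± 0.17) were also higher. Lower in knockouts were 9130214F15Rik (-2.60 ± 0.35), the kininogen gene Kng2 (-2.10 ± 0.38) and the monocarboxylate transporter Slc16a1 (-1.33 ± 0.16), of which Kng2 lay under the floor in all 3 knockout arrays (mean 4.57), so the size and rank of its difference are uncertain. The proton channel Otop1 (-1.50 ± 0.25) and the collagen Col12a1 (-1.35 ± 0.27) were lower too, with adjusted p of 0.00232 to 0.0503 and 0.00288 to 0.0673 over the alternatives, the highest when the saline groups were fitted alone. Of the 20 genes with the largest differences, 5 lost their call when 1 array was left out and are not described here.

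Mitochondrial lists were lower in knockouts after saline. The respiratory chain showed it most clearly, with the complex I subunit Ndufs8 (-0.70 ± 0.11). Respiratory chain genes had a median of -0.57, with camera adjusted p = 1.09e-15 and adjusted p = 0.571 with an estimated correlation. The tricarboxylic acid cycle was lower with the dehydrogenase Idh2 (-0.74 ± 0.10), mitochondrial maintenance with prohibitin Phb (-0.62 ± 0.095), and mitochondrial β-oxidation was lower too, although the outer-membrane carnitine transferase Cpt1a (0.55 ± 0.087) was higher. Of 13 tested tricarboxylic acid cycle genes, 6 were lower (12 adjusted over the list alone). Their median was -0.51, with camera adjusted p = 5.84e-05 and adjusted p = 0.571 with an estimated correlation. Of 24 tested mitochondrial maintenance genes, 10 were lower (13 adjusted over the list alone). Their median was -0.30, with camera adjusted p = 2.50e-05 and adjusted p = 0.571 with an estimated correlation. Of 22 tested mitochondrial β-oxidation genes, 1 was higher and 6 were lower (1 and 14 adjusted over the list alone). Their median was -0.41, with camera adjusted p = 5.84e-05 and adjusted p = 0.728 with an estimated correlation. Glucose metabolism genes were lower (median -0.19 after median-centring), with phosphofructokinase Pfkl (-0.72 ± 0.13). Of 36 tested glucose metabolism genes, 2 were higher and 9 were lower (2 and 10 adjusted over the list alone). Their median was -0.29, with camera adjusted p = 0.00349 and adjusted p = 0.571 with an estimated correlation. The brown adipocyte list was lower, with Letmd1 (-0.79 ± 0.13). Of 26 tested brown adipocyte genes, 2 were higher and 8 were lower (2 and 12 adjusted over the list alone). Their median was -0.52, with camera adjusted p = 0.0122 and adjusted p = 0.728 with an estimated correlation. The acetyl-CoA synthetase Acss1 (-0.79 ± 0.13), the glutathione peroxidase Gpx4 (-0.69 ± 0.099) and the adenylate cyclase Adcy3 (-0.70 ± 0.095) were also lower.

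Macrophage markers were higher as a list, including the cathepsin Ctss (1.51 ± 0.18). Of 20 tested macrophage markers, 14 were higher (15 adjusted over the list alone). Their median was 0.74, with camera adjusted p = 1.57e-13 and adjusted p = 0.301 with an estimated correlation. Fibroblast and matrix genes were higher, with periostin Postn (1.28 ± 0.19), the collagens Col1a2 (1.28 ± 0.19) and Col6a3 (0.58 ± 0.092) and the receptor Pdgfra (0.83 ± 0.13). Of 22 tested fibroblast and matrix genes, 16 were higher (17 adjusted over the list alone). Their median was 0.74, with camera adjusted p = 8.77e-14 and adjusted p = 0.301 with an estimated correlation. White adipocyte genes were higher, with Slc7a10 (1.34 ± 0.19), Ccdc80 (0.94 ± 0.16) and Trim14 (0.60 ± 0.095). Of 17 tested white adipocyte genes, 8 were higher (9 adjusted over the list alone). Their median was 0.57, with camera adjusted p = 4.83e-06 and adjusted p = 0.354 with an estimated correlation. Endoplasmic reticulum stress genes shifted slightly upward (4 of 21 higher at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05, median 0.23 after median-centring). Their median was 0.13, with camera adjusted p = 0.00752 and adjusted p = 0.728 with an estimated correlation. Among Schwann cell genes, Gldn (-1.24 ± 0.22) and S100b (-0.87 ± 0.13) were lower and Cdh19 (1.20 ± 0.21) was higher, from 2 of 3 wild-type arrays under the floor. The other lists did not pass camera (adjusted p from 0.0634 to 0.950). Of these, cAMP-responsive and immediate-early genes, fatty acid synthesis, lipolysis and lipid droplets, inflammatory genes, lymphocytes, skeletal muscle, proliferation and reference genes passed camera under at least 1 alternative.

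Limma's moderated test called 1849 of 15896 genes at an adjusted p under 0.05, 865 higher and 984 lower in knockouts, and 199 of them by at least 2-fold (154 higher and 45 lower). The count was 639 and 1161 without wild-type saline arrays 1 and 2, and 636 and 581 without knockout saline arrays 1 and 3, so the number of genes is the least certain of the 4 pairwise comparisons. Median-centring on all 115830 rows moved the share that was higher from 46.8% to 76.5%.

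After CL316243 the genotypes differed widely in brown fat identity. Of the 26 brown adipocyte genes tested 18 were lower in knockouts, among them Elovl3 at -2.91 ± 0.24 (n = 3 per group, adjusted p = 4.72e-05), Dio2 at -2.41 ± 0.48 (adjusted p = 0.00398), Prdm16 at -2.30 ± 0.11 and Ppargc1a at -1.64 ± 0.24. Of the respiratory chain genes 39 of 41 were lower. Gpnmb was 14.9-fold higher (3.90 ± 0.17, adjusted p = 1.43e-06), and 18 of 20 macrophage, 17 of 22 matrix and 11 of 17 white adipocyte genes were higher.

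The remaining large falls included 9130214F15Rik (-3.39 ± 0.35), the brown fat transcript Lncbate10 (-2.76 ± 0.42), Otop1 (-2.54 ± 0.25) and Plk3 (-2.50 ± 0.20), the pantothenate kinase Pank1 (-2.45 ± 0.24), the endocannabinoid lipase Dagla (-2.39 ± 0.11) and the lipid-sensing nuclear receptor Ppara (-2.37 ± 0.31). The fatty acid transporter Slc27a2 (-3.02 ± 0.36) was at -1.97 with the mean of its probe sets. Large rises were in Catspere2 (4.12 ± 0.72), at 1.42 with the mean of its probe sets, in Atp6v0d2 (2.84 ± 0.18) and Il7r (2.46 ± 0.36), and in genes of glandular epithelium, the casein Csn3 (2.95 ± 0.38), the serpin Serpinb5 (2.86 ± 0.44), the mucin Muc4 (2.72 ± 0.45), the chemokine Cxcl15 (2.68 ± 0.39) and Ly6d (2.58 ± 0.39). All 3 wild-type arrays lay under the expression floor for Csn3, Serpinb5 and Catspere2 (means 4.28, 4.16 and 3.68), and 2 of 3 knockout arrays for 9130214F15Rik (mean 5.20), so the sizes of these differences and their ranks are uncertain.

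The brown adipocyte list was lower in knockouts, with the cell-death-related lipid droplet gene Cidea (-1.89 ± 0.26) and the potassium channel Kcnk3 (-1.75 ± 0.14). Of 26 tested brown adipocyte genes, 2 were higher and 18 were lower (3 and 19 adjusted over the list alone). Their median was -1.22, with camera adjusted p = 1.12e-08 and adjusted p = 0.334 with an estimated correlation. The respiratory chain was lower across complexes, as in Cyc1 (-1.12 ± 0.15), Ndufb8 (-1.01 ± 0.14), Cox4i1 (-0.96 ± 0.12) and Sdha (-0.80 ± 0.099). Of 41 tested respiratory chain genes, 39 were lower (1 was higher and 39 were lower adjusted over the list alone). Their median was -0.75, with camera adjusted p = 8.16e-16 and adjusted p = 0.356 with an estimated correlation. The tricarboxylic acid cycle was lower with Suclg1 (-1.38 ± 0.19), Fh1 (-0.97 ± 0.14) and Cs (-0.91 ± 0.11), and mitochondrial β-oxidation with Acaa2 (-1.50 ± 0.20), Etfdh (-1.47 ± 0.19) and Hadha (-0.94 ± 0.17), again with Cpt1a (0.59 ± 0.087) higher. Of 13 tested tricarboxylic acid cycle genes, 12 were lower (12 adjusted over the list alone). Their median was -0.82, with camera adjusted p = 4.74e-07 and adjusted p = 0.356 with an estimated correlation. Of 22 tested mitochondrial β-oxidation genes, 1 was higher and 17 were lower (1 and 18 adjusted over the list alone). Their median was -0.85, with camera adjusted p = 5.79e-08 and adjusted p = 0.379 with an estimated correlation. Mitochondrial maintenance was lower, with the chaperone Hspd1 (-0.92 ± 0.16) and the protease Lonp1 (-0.66 ± 0.078). Of 24 tested mitochondrial maintenance genes, 1 was higher and 14 were lower (1 and 17 adjusted over the list alone). Their median was -0.38, with camera adjusted p = 4.61e-05 and adjusted p = 0.356 with an estimated correlation. Heat shock genes were lower, with Hsph1 (-1.40 ± 0.16), Hspa4l (-1.36 ± 0.20) and Dnajb1 (-0.96 ± 0.14). Of 12 tested heat shock genes, 10 were lower (10 adjusted over the list alone). Their median was -0.91, with camera adjusted p = 8.02e-05 and adjusted p = 0.356 with an estimated correlation.

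Further metabolic lists were lower by less. Peroxisomal oxidation was lower with Ehhadh (-1.81 ± 0.18) and Acot4 (-1.33 ± 0.17), PPAR targets with the glycerol channel Aqp7 (-1.27 ± 0.12) and Acot2 (-1.54 ± 0.13), and glucose metabolism with Ldhb (-1.43 ± 0.22), Slc16a1 (-1.24 ± 0.16) and Pfkl (-1.15 ± 0.13). Of 27 tested peroxisomal genes, 2 were higher and 15 were lower (2 and 15 adjusted over the list alone). Their median was -0.32, with camera adjusted p = 3.98e-04 and adjusted p = 0.440 with an estimated correlation. Of 19 tested PPAR targets, 1 was higher and 7 were lower (1 and 8 adjusted over the list alone). Their median was -0.30, with camera adjusted p = 0.00433 and adjusted p = 0.440 with an estimated correlation. Of 36 tested glucose metabolism genes, 2 were higher and 11 were lower (2 and 11 adjusted over the list alone). Their median was -0.27, with camera adjusted p = 0.00998 and adjusted p = 0.428 with an estimated correlation. Median-centring gave these 3 lists medians of -0.21, -0.19 and -0.16. cAMP-responsive genes were lower with Nr4a2 (-1.92 ± 0.21), Gem (-1.22 ± 0.19) and Atf3 (-1.12 ± 0.18), with medians of -0.15 after median-centring and -0.47 with the muscle covariate, and lost the call without wild-type CL316243 array 1 (adjusted p = 0.0845), with no filter (0.0615) and with the mean of each gene's probe sets (0.0527, 4.72e-04 to 0.0845 over the alternatives). Of 35 tested cAMP-responsive genes, 2 were higher and 13 were lower (2 and 14 adjusted over the list alone). Their median was -0.26, with camera adjusted p = 0.0228 and adjusted p = 0.681 with an estimated correlation. Endothelial markers were lower with Kdr (-0.59 ± 0.11) and Tie1 (-0.50 ± 0.12), with a median of -0.13 after median-centring, and lost the call without knockout CL316243 array 2 (adjusted p = 0.0734, 0.00182 to 0.0734 over the alternatives). Of 17 tested endothelial markers, 2 were higher and 6 were lower (2 and 8 adjusted over the list alone). Their median was -0.24, with camera adjusted p = 0.0207 and adjusted p = 0.591 with an estimated correlation. Adenylate cyclase Adcy3 (-1.84 ± 0.095), the stimulatory G protein Gnas (-0.74 ± 0.12) and the anchor Akap1 (-1.27 ± 0.16) were lower although the adrenergic signalling list did not pass.

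Macrophage markers were higher, with the pore-forming Mpeg1 (2.19 ± 0.23) and Cd68 (1.22 ± 0.12). Of 20 tested macrophage markers, 18 were higher (18 adjusted over the list alone). Their median was 1.13, with camera adjusted p = 6.58e-13 and adjusted p = 0.334 with an estimated correlation. Fibroblast and matrix genes were higher with Mmp3 (2.12 ± 0.21), Dpt (1.26 ± 0.16) and Pdgfra (1.04 ± 0.13), and white adipocyte genes with resistin Retn (1.97 ± 0.20), Slc7a10 (1.84 ± 0.19) and Ccdc80 (1.79 ± 0.16) and leptin Lep (0.77 ± 0.18). Of 22 tested fibroblast and matrix genes, 17 were higher (18 adjusted over the list alone). Their median was 0.90, with camera adjusted p = 3.99e-10 and adjusted p = 0.334 with an estimated correlation. Of 17 tested white adipocyte genes, 11 were higher (12 were higher and 2 were lower adjusted over the list alone). Their median was 0.93, with camera adjusted p = 1.34e-06 and adjusted p = 0.334 with an estimated correlation. Inflammatory genes were higher, with Lcn2 (1.85 ± 0.40), Ccl3 (1.27 ± 0.23) and Tnf (1.06 ± 0.26), at 0.36 without knockout CL316243 array 2. Of 28 tested inflammatory genes, 10 were higher (11 adjusted over the list alone). Their median was 0.57, with camera adjusted p = 8.02e-05 and adjusted p = 0.428 with an estimated correlation. The adipokine Adipoq (0.67 ± 0.11) and the growth factor Igf1 (1.45 ± 0.13) were higher as well. Lymphocyte markers, 2 of which were higher at an unadjusted p under 0.05, lost their call without knockout CL316243 array 2 (median 0.083) or wild-type CL316243 arrays 1 or 2 (0.42 and 0.42), after median-centring (0.57) and with the stricter filter (0.63), and were at 0.79 without knockout CL316243 array 1. Of 16 tested lymphocyte markers, 2 were higher (0 adjusted over the list alone). Their median was 0.46, with camera adjusted p = 0.0335 and adjusted p = 0.681 with an estimated correlation. Proliferation genes lost their call without knockout CL316243 array 2 (0.12) or wild-type CL316243 array 2 (0.20) and with the stricter filter (0.11), and were at 0.14 with the mean of each gene's probe sets. Of 19 tested proliferation genes, 4 were higher (3 adjusted over the list alone). Their median was 0.23, with camera adjusted p = 0.0244 and adjusted p = 0.681 with an estimated correlation.

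Skeletal muscle markers had the largest median, but 0 of 22 passed limma's test and 1 had an unadjusted p under 0.05. Their median was 1.72, with camera adjusted p = 0.0113 and adjusted p = 0.681 with an estimated correlation. The call ended without wild-type CL316243 array 1 (median 1.16), after median-centring (1.83), with the muscle covariate (0.048) and with array weights (0.998), so it depended on single arrays and settings. The other lists did not pass (adjusted p from 0.0541 to 0.852). Of these, adrenergic signalling and cholesterol synthesis passed camera under at least 1 alternative. Limma's moderated test called 4685 of 15896 genes at an adjusted p under 0.05, 2329 higher and 2356 lower in knockouts, and 562 of them by at least 2-fold (363 higher and 199 lower). Median-centring moved the median difference of all genes from -0.042 to 0.070 and the share that was higher from 49.7% to 72.0%, so the differences above are relative to the deposited scaling. Knockout effects after saline and after CL316243 share no arrays: 654 genes were higher and 582 lower in both, against 127 and 146 under independence, and 25 were called in opposite directions (Pearson r = 0.628).

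**Figure D2:**
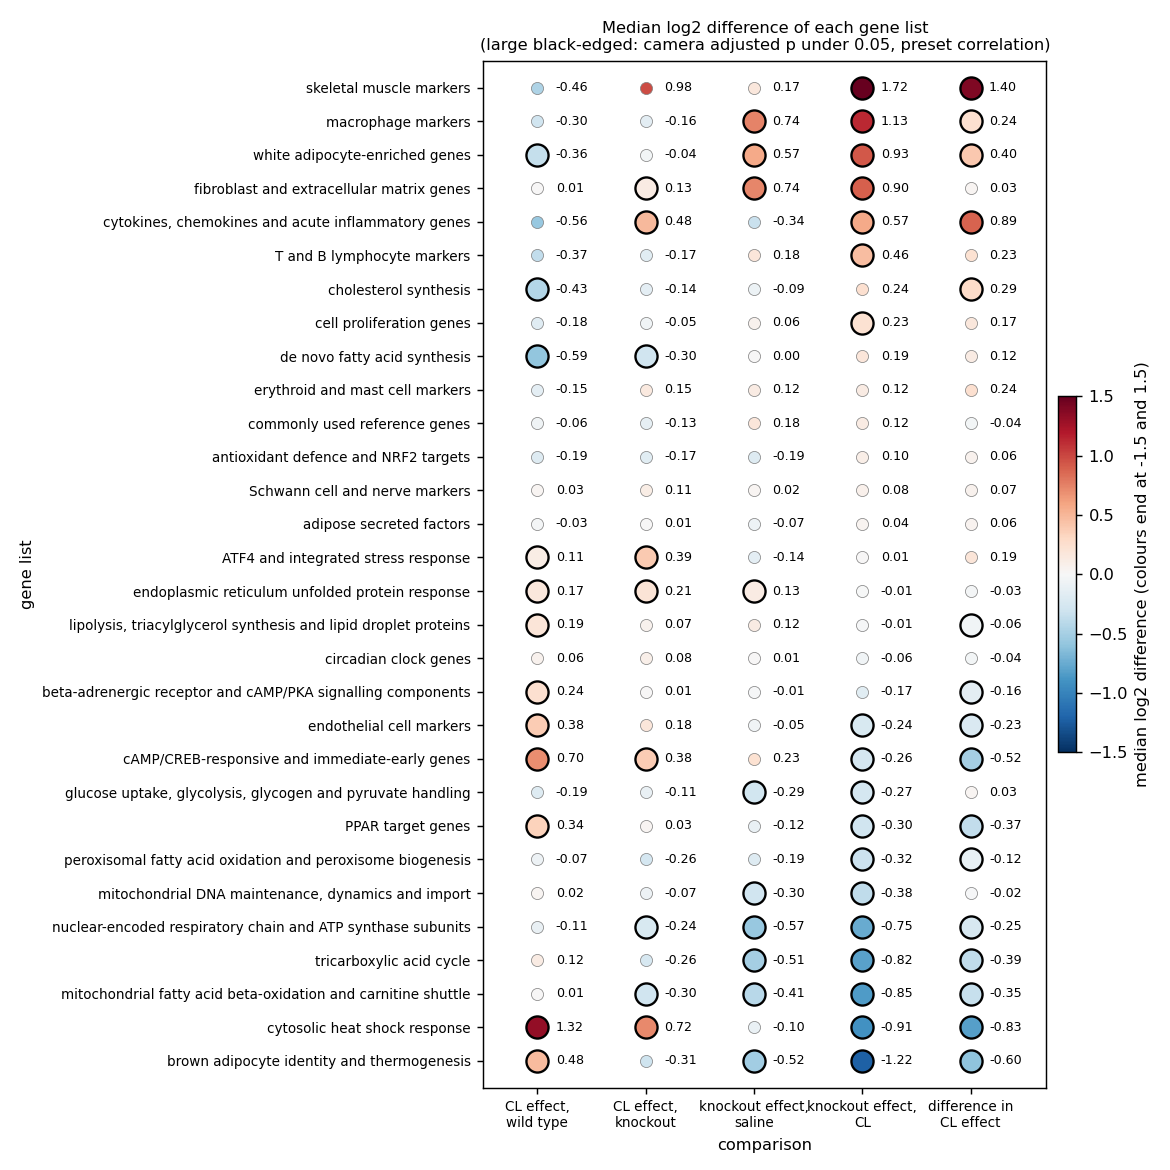
Median log2 difference of the genes of each of the 30 lists (rows) in the 5 comparisons (columns, n = 3 arrays per group). Large black-edged circles mark a camera adjusted p under 0.05 with the preset correlation, and the brown adipocyte list was at 0.48 for the agonist in wild types and at -1.22 for the knockout after CL316243.

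The response to the agonist differed between genotypes for 324 genes, mostly through a smaller rise or a fall in knockouts of genes that rose in wild types. Prdm16 is an example from the brown adipocyte list: it rose by 1.36 ± 0.11 in wild types against a knockout change of -0.58 ± 0.11 (-0.21 with the mean of its probe sets), which gives a difference in response of -1.95 ± 0.16 (log2, adjusted p = 2.26e-04, n = 3 arrays in each of 4 groups). The kinase Plk3 rose by 3.77 ± 0.20 in wild types, with a difference of -2.41 ± 0.28 (adjusted p = 0.00270), and the adaptor Irs2 rose by 2.95 ± 0.27, with a difference of -2.35 ± 0.38 (adjusted p = 0.0128). Prg4 went the other way, with a rise of 3.37 ± 0.14 in knockouts and a difference of 1.75 ± 0.19 (adjusted p = 0.00209).

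Further genes with a more negative response in knockouts were the transporter Mfsd2a (-2.52 ± 0.31), the fatty acid receptor Ffar4 (-2.52 ± 0.21), the pyruvate dehydrogenase phosphatase Pdp2 (-2.45 ± 0.22), 3930402G23Rik (-2.28 ± 0.27), the peroxisomal enzyme Ehhadh (-2.20 ± 0.25), Dagla (-2.07 ± 0.16) and the ubiquitin ligase adaptor Fbxo21 (-1.98 ± 0.21). The same held for the early genes Gem (-1.88 ± 0.27), Nr4a2 (-1.84 ± 0.30) and Atf3 (-1.53 ± 0.26), the thioesterases Acot4 (-1.57 ± 0.24), Acot2 (-1.12 ± 0.18) and Acot8 (-0.79 ± 0.13), the cyclase Adcy3 (-1.15 ± 0.13) and the brown fat factor Ebf2 (-0.86 ± 0.13). Genes with a more positive response in knockouts were Apol6 (2.02 ± 0.33), Fam110c (1.94 ± 0.24), 5830467E07Rik (1.76 ± 0.28), Nav3 (1.74 ± 0.25) and Plac8 (1.72 ± 0.19) and the lipopolysaccharide co-receptor Cd14 (1.36 ± 0.21), with the size for Fam110c again uncertain. Ppargc1a (-1.54 ± 0.33) and Elovl3 (-1.89 ± 0.34) also responded less in knockouts, with calls that depended on the single arrays named in the closing section (adjusted p = 0.0135 to 0.104 and 0.00777 to 0.0605 over the alternatives). By class, 190 of the genes rose in wild types with a smaller rise or a fall in knockouts, 72 fell in wild types with a smaller fall or a rise in knockouts, 55 were called in knockouts alone and 7 moved further in the same direction in knockouts.

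As lists, the brown adipocyte genes responded less in knockouts, at -0.97 without knockout saline array 1, as did cAMP-responsive genes, heat shock genes and adrenergic signalling. Of 26 tested brown adipocyte genes, 6 responded more negatively (15 adjusted over the list alone). Their median was -0.60, with camera adjusted p = 7.21e-11 and adjusted p = 0.315 with an estimated correlation. Of 35 tested cAMP-responsive genes, 1 responded more positively and 7 responded more negatively (2 and 9 adjusted over the list alone). Their median was -0.52, with camera adjusted p = 1.18e-05 and adjusted p = 0.559 with an estimated correlation. Of 12 tested heat shock genes, 3 responded more negatively (9 adjusted over the list alone). Their median was -0.83, with camera adjusted p = 5.71e-07 and adjusted p = 0.315 with an estimated correlation. Of 24 tested adrenergic signalling genes, 1 responded more negatively (1 adjusted over the list alone). Their median was -0.16, with camera adjusted p = 0.00280 and adjusted p = 0.315 with an estimated correlation. Inflammatory genes responded more positively. Of 28 tested inflammatory genes, 1 responded more positively (15 adjusted over the list alone). Their median was 0.89, with camera adjusted p = 8.32e-10 and adjusted p = 0.315 with an estimated correlation. The tricarboxylic acid cycle and cholesterol synthesis shifted without a member past limma's test, while 4 of 13 and 6 of 19 members had an unadjusted p under 0.05. Tricarboxylic acid cycle genes had a median of -0.39, with camera adjusted p = 7.05e-04 and adjusted p = 0.559 with an estimated correlation. Cholesterol synthesis genes had a median of 0.29, with camera adjusted p = 0.00520 and adjusted p = 0.559 with an estimated correlation. Mitochondrial β-oxidation was at -0.22 and PPAR targets at -0.13 without knockout saline array 2, and the latter at -0.21 without knockout CL316243 array 2. Of 22 tested mitochondrial β-oxidation genes, 2 responded more negatively (6 adjusted over the list alone). Their median was -0.35, with camera adjusted p = 4.37e-05 and adjusted p = 0.559 with an estimated correlation. Of 19 tested PPAR targets, 3 responded more negatively (5 adjusted over the list alone). Their median was -0.37, with camera adjusted p = 7.13e-05 and adjusted p = 0.559 with an estimated correlation. The other lists did not pass (adjusted p from 0.145 to 0.564), and 7 further lists are given with their dependence on single arrays in the closing section. Of the lists without a call, fatty acid synthesis, endoplasmic reticulum stress, antioxidant defence, lymphocytes and proliferation passed camera under at least 1 alternative.

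Of the 21 tested panel genes, 11 were called for the agonist in wild types, 9 for the agonist in knockouts, 7 for genotype after saline, 12 for genotype after CL316243 and 3 for the interaction, and 6 were called in none of them by limma. Those without a call were Ucp1, given above, and Nr4a1, Pdk4, Angptl4, Fasn and Scd1. In wild types the agonist effect, with the range of adjusted p over the alternatives, was 0.90 (adjusted p = 0.118, 0.00374 to 0.241) for the early gene Nr4a1, 1.08 (adjusted p = 0.0689, 3.68e-04 to 0.145) for the pyruvate dehydrogenase kinase Pdk4, -0.13 (adjusted p = 0.817, 0.613 to 0.968) for the lipase inhibitor Angptl4, -0.84 (adjusted p = 0.0513, 0.0332 to 0.188) for fatty acid synthase Fasn and 0.17 (adjusted p = 0.250, 0.106 to 0.583) for the desaturase Scd1. Genotype differences after CL316243 were -0.61 (adjusted p = 0.263), -1.01 (adjusted p = 0.0843), 0.037 (adjusted p = 0.940), 0.84 (adjusted p = 0.0512) and -0.020 (adjusted p = 0.892) for the same genes, of which Nr4a1, Pdk4 and Fasn passed under some alternatives. Without knockout saline array 1, Nr4a1 and Pdk4 passed in wild types (adjusted p = 0.00452 and 3.68e-04) and in the interaction (-1.76 and -1.14), so their lack of a call depended on that array. Nr4a1 then also passed for genotype after saline (1.15 against 0.54) and for the agonist in knockouts (-0.86 against -0.25). Angptl4 was at -0.87 (adjusted p = 0.106, 0.0143 to 0.249) for genotype after saline and 0.78 (adjusted p = 0.125, 0.0197 to 0.348) for the agonist in knockouts, and without knockout saline array 2 both passed (-1.26 and 1.17), as did Ucp1 after saline (-2.61 against -1.82).

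Other panel calls depended on single arrays (ranges are of adjusted p over the alternatives). For the agonist in wild types the call was lost for Dio2 (1.67 ± 0.48, 3.73e-04 to 0.0628) without wild-type saline arrays 1 or 3 or wild-type CL316243 arrays 2 or 3 and for Acadm (-0.34 ± 0.11, 0.00580 to 0.115) without wild-type saline arrays 1 or 2 or wild-type CL316243 arrays 1, 2 or 3. For the agonist in knockouts it was lost for Cidea (-0.91 ± 0.26, 0.00799 to 0.121) without knockout saline arrays 2 or 3 or knockout CL316243 arrays 1 or 3 and for Nr4a3 (1.44 ± 0.36, 0.00106 to 0.0682) without knockout saline array 3 or knockout CL316243 arrays 1 or 3, which was at 0.96 without knockout saline array 1. For genotype after saline it was lost for Elovl3 (-1.02 ± 0.24, 0.00526 to 0.105) without wild-type saline array 1 or knockout saline arrays 1 or 3, for Cidea (-1.09 ± 0.26, 0.0106 to 0.126) without wild-type saline arrays 1 or 2 or knockout saline arrays 1 or 3 and for Acadm (-0.49 ± 0.11, 0.00532 to 0.118) without wild-type saline arrays 1 or 2 or knockout saline arrays 1 or 3. The same held for Adipoq (0.47 ± 0.11, 0.00795 to 0.0822) without wild-type saline arrays 1 or 3 or knockout saline arrays 1 or 3 and for Plin2 (0.41 ± 0.12, 0.0271 to 0.140) without wild-type saline arrays 2 or 3, wild-type CL316243 arrays 1 or 2, knockout saline arrays 2 or 3 or knockout CL316243 arrays 1, 2 or 3. With 1 array left out, Irf4 (0.99 ± 0.28, 0.0192 to 0.125) kept its call after saline only without knockout saline arrays 1 or 2. The difference was 0.59 without array 2. Panel calls kept with each array left out and not given above were Adipoq (-0.42 ± 0.11, adjusted p = 0.0583 when the 2 groups were fitted alone, 0.00926 to 0.0583 over the alternatives) for the agonist in wild types, Plin2 (0.89 ± 0.12) and Lep (-0.99 ± 0.18) for the agonist in knockouts and Fgf21 (-0.46 ± 0.11) and Acadm (-0.65 ± 0.11) for genotype after CL316243.

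The interaction test called 324 of 15896 genes, 123 with a more positive and 201 with a more negative response in knockouts, 119 of them by at least 2-fold. It combines the errors of 4 groups, and on simulated data it recovered 81.0% of differences of 1 log2 unit and 0% of those of 0.5. The count was 184 and 181 without wild-type saline arrays 1 and 3, 128 without wild-type CL316243 array 2, 180 and 175 without knockout saline arrays 2 and 3, and 158 and 129 without knockout CL316243 arrays 2 and 3. Of these genes, 46 were called in opposite directions in the 2 genotypes.

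**Figure D3:**
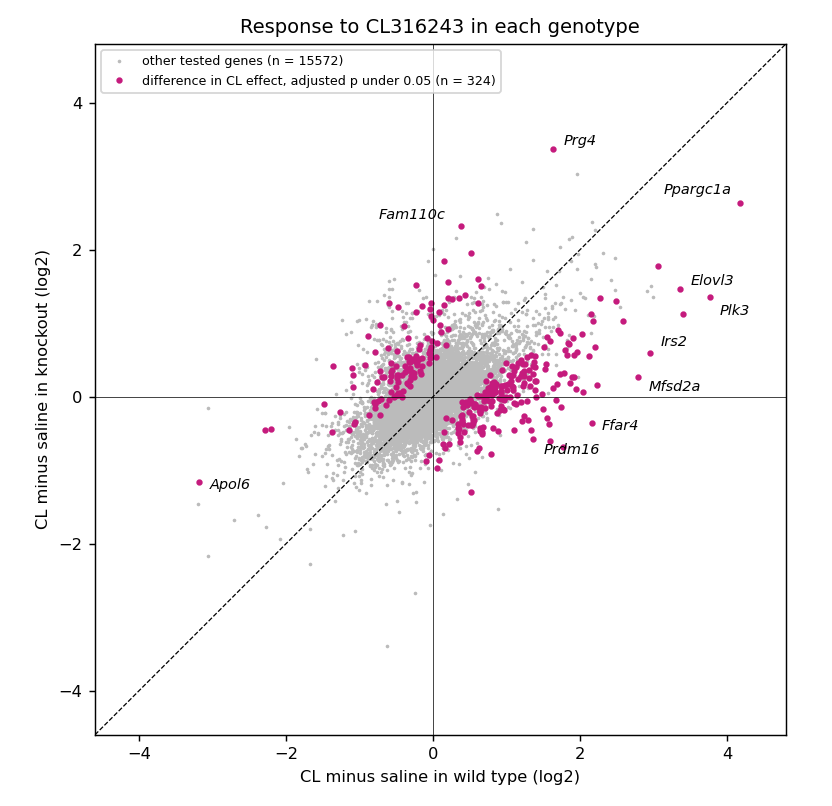
Log2 difference between CL316243 and saline in wild types (horizontal) and in knockouts (vertical) for each of the 15896 tested genes, with the line of equal response dashed. The 324 genes whose response differed at an adjusted p under 0.05 are coloured, and most lie below the line on the right.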

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

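The tests that compared macrophage with endothelial markers, and those of the cAMP and brown adipocyte lists against a raised starting level, were chosen only after the results they bear on had been seen, and the skeletal muscle covariate and the list of mammary epithelial genes were also chosen after the data had been seen.

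The effect of CL316243 differed between genotypes by an interaction test for 324 genes. The most negative differences in response, knockout minus wild type on the log2 scale, were Mfsd2a (-2.52), Ffar4 (-2.52), Pdp2 (-2.45), Plk3 (-2.41), Irs2 (-2.35), 3930402G23Rik (-2.28), Ehhadh (-2.20), Dagla (-2.07), Fbxo21 (-1.98) and Prdm16 (-1.95), and the most positive were Apol6 (2.02), Fam110c (1.94), Ccl12 (1.87), Gbp2 (1.83), Serpinb10 (1.78), 5830467E07Rik (1.76), Prg4 (1.75), Nav3 (1.74), Plac8 (1.72) and Ch25h (1.70). Of the panel genes, Ppargc1a (-1.54) and Elovl3 (-1.89) differed as well. Serpinb10 lay under the expression floor in all arrays of 2 groups, wild-type CL316243 and knockout saline (means 4.52 and 4.96), and Fam110c in 2 of 3 knockout saline arrays (mean 5.34), so the sizes of their differences are uncertain. Some of these calls rested on single arrays. Ppargc1a kept its call without wild-type CL316243 array 3 or knockout saline arrays 1 or 2 and lost it without each of the other 9 (adjusted p = 0.0135 to 0.104 over all alternatives). Ccl12 kept it without wild-type saline array 3, knockout saline arrays 1 or 3 or knockout CL316243 array 1 and lost it without each of the other 8 (0.0194 to 0.0925). Serpinb10 kept it without wild-type saline array 2, knockout saline arrays 1 or 3 or knockout CL316243 arrays 1 or 2 and lost it without each of the other 7 (0.0157 to 0.0795), and Ch25h kept it without array 1 of either CL316243 group and lost it without each of the other 10 (0.0153 to 0.117). Elovl3 lost its call without wild-type CL316243 array 2, knockout saline array 2 or knockout CL316243 array 2, and Gbp2 without wild-type CL316243 array 2 (0.00777 to 0.0605 and 0.00224 to 0.0575 over the alternatives).

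By camera 16 lists also differed in response, 3 of them by fry and 0 with an estimated correlation (lowest adjusted p = 0.315). The medians of the difference were -0.60 for brown adipocyte genes, -0.52 for cAMP-responsive genes, -0.83 for heat shock, -0.16 for adrenergic signalling, -0.35 for mitochondrial β-oxidation, -0.37 for PPAR targets, -0.39 for the tricarboxylic acid cycle, 0.29 for cholesterol synthesis and 0.89 for inflammatory genes. Another 7 lists passed with camera and depended on single arrays. The respiratory chain (-0.25, adjusted p = 6.45e-04, adjusted p = 0.744 with an estimated correlation) was at -0.16 without wild-type saline array 3 and at -0.11 and not called without knockout saline array 2. Endothelial markers (-0.23, adjusted p = 0.00101, adjusted p = 0.559 with an estimated correlation) were at -0.13 and -0.14 without array 2 of knockout saline and of knockout CL316243.

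Of the remaining lists, peroxisomal oxidation (-0.12, adjusted p = 7.05e-04, adjusted p = 0.559 with an estimated correlation) was at -0.20 and -0.051 without wild-type saline arrays 2 and 3, -0.070 without wild-type CL316243 array 2 and -0.058 without knockout saline array 2, and at -0.19 with array weights and -0.074 with the muscle covariate. Lipolysis and lipid droplets (-0.058, adjusted p = 0.00768, adjusted p = 0.603 with an estimated correlation) ran from -0.14 to -0.021 over the alternatives and lost its call without wild-type saline array 3 (-0.033). White adipocyte genes (0.40, adjusted p = 0.0181, adjusted p = 0.559 with an estimated correlation) lost theirs without wild-type saline array 3 (0.39), wild-type CL316243 array 1 (0.31), knockout saline array 3 (0.37) or knockout CL316243 array 1 (0.35), and with array weights (0.26). Macrophage markers (0.24, adjusted p = 0.0418, adjusted p = 0.733 with an estimated correlation) lost theirs without wild-type saline array 2 (0.074), wild-type CL316243 array 3 (0.22), knockout saline array 2 (0.11) or knockout CL316243 arrays 1 (0.20) or 2 (0.18), and with array weights (0.090), median-centring (0.26) or the stricter filter (0.24). Skeletal muscle markers (1.40, adjusted p = 0.0250, adjusted p = 0.749 with an estimated correlation) lost theirs without wild-type saline array 3 (0.29), wild-type CL316243 arrays 1 (0.89) or 3 (1.38), knockout saline array 1 (0.31) or knockout CL316243 arrays 1 (1.10) or 3 (1.12), were not called with array weights (0.49), the stricter filter (1.40) or the muscle covariate (-0.024), and were at 2.40 without wild-type saline array 2. Skeletal muscle, respiratory chain, tricarboxylic acid, cholesterol and white adipocyte genes had 0 members past limma's interaction test, and 0, 5, 4, 6 and 6 with an unadjusted p under 0.05 in the direction of the list.

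Signal also appeared in transcript clusters outside the comparisons, those not assigned to a single gene. Of 47841 such clusters tested in the same way, 4240 changed after CL316243 in wild types, 1042 after CL316243 in knockouts, 182 differed by genotype after saline and 1775 by genotype after CL316243. They are absent from the probe table used here or listed there with several genes, and were not resolved further.

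The difference in response to CL316243 between genotypes was weighed against chance and against features of the arrays. Of 100 arrangements of genotype among arrays of the same treatment, the real one included, 3 called at least the real 324 genes (highest 1756). Those that mixed the CL316243 arrays of the 2 genotypes all called 0. The 7 that kept them together, these 3 among them, also kept the genotype difference after CL316243, so the comparison cannot decide on chance. Without knockout saline array 1, whose Ucp1 and Dio2 stood apart, 298 genes were called, which argues against that array as the cause. A raised level before stimulation could also shrink a response, but brown adipocyte genes were lower in knockouts at both times (mean -1.23 ± 0.18 after CL316243 and -0.46 ± 0.18 after saline, or -0.25 ± 0.12 without knockout saline array 1), which argues against it for that list. For cAMP-responsive genes (mean -0.35 ± 0.19 after CL316243, 0.20 after saline, 0.43 and -0.011 without knockout saline arrays 1 and 2) it stays open. Their saline median of 0.23 did not pass camera (adjusted p = 0.0634, 1.54e-07 to 0.894 over the alternatives, 0.965 with an estimated correlation), but was 0.40 and passed without knockout saline array 1, passed without wild-type saline arrays 1 or 3, with no filter and with the mean of each gene's clusters, and was 0.0033 without knockout saline array 2. Also open is a weaker signal from the receptor or a smaller share of responding adipocytes, neither of which was tested.

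The pairwise counts were set against other splits of the same 6 arrays into 3 and 3, with 10 splits each, the real one included. The real split alone gave as many genes each time. For CL316243 it gave 4735 against a highest other of 0 in wild types and 2851 against 2 in knockouts. For genotype it gave 1849 against 1 after saline and 4685 against 0 after CL316243. With 10 splits these are too few for a share under 0.05.

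In knockouts, lower brown adipocyte and mitochondrial lists came with higher macrophage, matrix and white adipocyte lists. A lower share of brown adipocytes would raise every other cell type alike, yet after saline the mean shift of macrophage markers exceeded that of endothelial markers by 0.90 ± 0.18 (log2), which argues against this as the whole cause. More skeletal muscle RNA in knockout dissections was tested with the muscle covariate, and the brown adipocyte list stayed lower after CL316243 at a median of -1.26 (standard error of its mean 0.20, camera adjusted p = 7.29e-09, adjusted p = 0.373 with an estimated correlation), which argues against muscle as the cause. A gain of macrophages and fibroblasts, and a change of expression within adipocytes that lack Cpt2, may both contribute, and bulk tissue does not separate them.

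Csn3, Muc4, Serpinb5, Cxcl15 and Ly6d, genes of glandular epithelium, were higher in knockout arrays after CL316243, and a candidate source is mammary or other epithelial tissue taken with the fat pad of these female mice. A list of mammary epithelial genes written after these 5 were seen, without them, had a mean difference of 0.93 ± 0.21, with 19 of 28 tested genes higher (20 adjusted over the list alone, camera adjusted p = 1.60e-08, adjusted p = 0.284 with an estimated correlation). After saline the list was higher in knockouts too (mean 0.47 ± 0.21, 0.31 without knockout saline array 3, 3 genes higher, 6 adjusted over the list alone, camera adjusted p = 1.31e-05, adjusted p = 0.270 with an estimated correlation). The values fit more epithelial RNA in knockout than in wild-type dissections, and whether it entered at dissection or reflects a change in the knockout depot was not tested.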

How the results depend on the processing

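The muscle covariate and the gene-by-gene array weights were chosen after the data had been seen, and the cause of the changes below was not tested except where the construction shows it. The interaction count of 324 was 172 after median-centring, 497 with the stricter filter and 978 with array weights. The genotype count after saline, 1849, was 604 when the saline groups were fitted alone, 3400 with array weights and 527 with the muscle covariate and without knockout saline array 1. Stricter thresholds lower the counts by construction: at least 2-fold gave 458, 233, 199, 562 and 119, and an adjusted p under 0.01 gave 2629, 1119, 418, 2255 and 52, for CL316243 in wild types and knockouts, genotype after saline and CL316243, and the interaction. Leaving out 1 array at a time gave 3531 to 4709, 1591 to 3358, 581 to 2458, 3232 to 4742 and 128 to 399 genes in that order, and Cpt2 differences of -0.80 to -0.68 after saline and -0.82 to -0.66 after CL316243. The skeletal muscle list of the interaction went from 1.40 to -0.024 with the muscle covariate, which removes those genes' own mean by construction. With replicate number as a block the counts were 4662, 2796, 1758, 4723 and 292. After group means were removed, 7 of 18 same-number pairs had r above 0.1 (-0.298 to 0.476) and 7 of 12 arrays correlated best with their own number, so the numbers were not taken to pair samples. Over all alternatives, the 490 of 730 named gene results that were called kept their call 10808 times and lost it 892 times, and the others gained one 311 times. The 65 of 150 list results called by camera kept their call 1243 times and lost it 122 times, 65 of them with the estimated correlation and 1 with its sign reversed, the skeletal muscle list above, and the others gained a call 66 times. Median, mean and camera direction differed in sign for 16 of 150 list results, 0 of them called by camera.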

Other observations

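The 3 lists in this part and their tests were drawn up after Gbp11, Apol6, Gpnmb and the immunoglobulin genes had been seen. In wild types 20 of 33 interferon-responsive genes, which encode antiviral and antigen-presentation proteins, fell after CL316243 (28 adjusted over the list alone, median -0.80, camera adjusted p = 4.46e-07, adjusted p = 0.846 with an estimated correlation). After CL316243 26 of them were higher in knockouts than in wild types (29 adjusted over the list alone, median 1.03, camera adjusted p = 1.52e-12, adjusted p = 0.284 with an estimated correlation). After saline 6 were higher (12 adjusted over the list alone, median 0.48, camera adjusted p = 2.46e-06, adjusted p = 0.270 with an estimated correlation). In knockouts 2 fell after CL316243, with a list median of -0.26 (camera adjusted p = 0.107) that passed without wild-type saline array 2, knockout saline array 1 (-0.43) or knockout CL316243 array 1 (-0.38) and was -0.16 and -0.067 without array 3 of knockout saline and of knockout CL316243. The difference in response had a median of 0.52 (camera adjusted p = 1.96e-06, adjusted p = 0.565 with an estimated correlation), with 0 of 33 genes past limma's interaction test and 7 at an unadjusted p under 0.05.

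Lysosomal genes were higher in knockouts after saline (14 higher and 1 lower of 45, 19 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 1.39e-11, adjusted p = 0.137 with an estimated correlation). After CL316243 18 were higher and 7 lower (median 0.25, camera adjusted p = 0.00210, adjusted p = 0.344 with an estimated correlation), with a median of 0.16 without wild-type CL316243 array 3. Of 18 plasma cell genes 3 were higher after saline (4 adjusted over the list alone, median 0.19, camera adjusted p = 1.69e-04, adjusted p = 0.137 with an estimated correlation), with medians of 0.32 and 0.046 without knockout saline arrays 1 and 3, and 6 were higher and 1 lower after CL316243.

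A candidate explanation for the fall of Gbp2, Gbp11, Apol6, Tnfsf10 and BC023105 after CL316243 in wild types is a fall of interferon-responsive genes as a class, and the list, which excludes those 5 genes, had a mean shift of -0.88 ± 0.24, beyond the bound of -0.20 set before its result was seen. A lysosomal class rise was weighed for Gpnmb (3.96 to 4.15 over the alternatives) and Atp6v0d2 (2.74 to 3.07) in knockouts after saline. The lysosomal list's mean shift of 0.29 ± 0.057 did not clear the bound of 0.20 by 2 standard errors. The test therefore leaves a class rise open. Plasma cells could carry the immunoglobulin kappa genes. Their list had a mean shift of 0.31 ± 0.13, or 0.20 without knockout saline array 3, against a bound of 0.50, leaving this open. The tissue was not sorted, and macrophages also express lysosomal genes, so these lists do not separate cell types from states.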
